A study of Homo sapiens with 5 samples.

How the data were processed

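Per the labels' protocols, U937 cells were heated at 42 °C for 90 min and recovered at 37 °C, total RNA was purified on RNeasy columns and treated with DNase, and labelled cRNA made from 5 µg of it was hybridised to U133 Plus 2.0 arrays. The deposited table gave 1 linear intensity for each of 54675 probe sets on each of 5 arrays. The software and the scaling that produced these values are not given in the sources used here, and the raw scans were not analysed here. The values showed no common level, as hybridisation controls moved by -0.46 log2 at 6 h and the median gene by -0.68 log2 at 3 h.

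Probe sets were named through the array's table of gene identifiers, as annotated in 2016, and symbols were updated through a RefSeq gene table of GRCh38.p14, which served for names only. Apart from 62 control probe sets, 41097 of 54613 had 1 gene, 1801 had several and 11721 had none. The 19775 genes that were left did not include HSPA1A, HSPA1B or HSPA8, whose probe sets are shared between genes or unassigned in that table. HSPA6 is nearly identical to the pseudogene HSPA7, and its probe sets may detect both.

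The following was fixed before the data were examined. Values below a floor, the median of all probe sets pooled over the arrays (intensity 17.1, or 4.10 log2), were set to the floor, and genes under it on both arrays of a comparison were left out. Each gene was represented by its brightest single-gene probe set, with cross-hybridising probe sets used where no other existed. The log2 difference between 2 arrays was the measure, and 2-fold was the threshold. Where an intensity was at the floor on 1 side, the fold is a bound and is printed as at least that value. With 1 array in each group there was no replicate error, and leave-one-out runs and tests could not be made.

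Also fixed beforehand were 33 gene lists, covering chaperone families, stress and inflammatory pathways, metabolism, the cell cycle, translation, cell type markers and large gene families. The median change of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and called apart at percentiles of 2.5 or less or 97.5 or more. A shift of a whole array can move percentiles through the floor, and median centring added 4 list calls and ended 2. The scale relative to the median gene cannot move them and is not counted among the 11 alternatives for list calls. Lists with fewer than 5 measured genes got no percentile. Some genes belong to more than 1 list, and genes of a list that are regulated together make extreme percentiles more frequent than 5.0%.

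Genes were named by a rule set beforehand, the 12 largest rises and 8 largest falls at each time whose probe sets had the same direction, 4 of each between consecutive times, and up to 5 members with the largest differences from each list, plus any member of the 4 chaperone lists. Among the genes so named, those in the text were chosen after the values were seen. The scale relative to the median gene, median centring with a higher floor and centring on hybridisation controls were added after the values were seen.

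Arrays were simulated with normally distributed noise of the SDs given below. Among 12430 simulated genes, 251 unchanged ones (2.05% of the unchanged) passed 2-fold, 16 passed 4-fold, and 6 passed 2-fold with the floor at the 70th percentile. Of 40 genes moved by 1.5 log2, 95.0% of rises and 77.5% of falls were found, and 85.0% of falls of 2 log2. Unchanged lists of 20 genes were called in 5.0% of draws, and lists moved by 0.5 log2 were called in 100% of draws. This noise was taken from differences between the changes of the 2 brightest probe sets of a gene, which gave a robust SD of 1 probe set of 1.48 log2 below the floor, 0.49 log2 up to 64, 0.30 log2 up to 256, 0.20 log2 up to 1024 and 0.12 log2 above, and does not contain the spread between cultures. The real differences had more extreme values than normal noise of these SDs. The 95th percentile of their absolute size was 0.71 log2 at intensities from 64 to 256 and 0.32 log2 above 1024. The simulated numbers of unchanged genes past a threshold may therefore be too low. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.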

Results

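Gene expression was measured in U937, a cell line with monocytic features that was derived from a human lymphoma, before and after a mild heat treatment. Cells were held at 42 °C for 90 min and returned to 37 °C for 0, 1, 3 or 6 h, and untreated cells were the control. Each of the 5 conditions was measured on 1 array of the U133 Plus 2.0 type, so no test was possible and the number of arrays limits the precision of every value.

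The arrays differed in their general level. Median intensities were 19.7 in control cells and 19.6, 19.1, 12.7 and 15.5 at 0, 1, 3 and 6 h, and the median gene moved by -0.04, -0.21, -0.68 and -0.58 log2 against control. Folds below are therefore given relative to the median gene of each comparison, next to intensities as deposited. A gene is said to have risen if it was at least 2-fold brighter as deposited, and to have fallen if it was at least 2-fold dimmer relative to the median gene. The change of a single probe set had a technical SD of 0.30 log2 at intensities from 64 to 256 and of 0.12 log2 above 1024, estimated from genes with several probe sets.

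**Figure D1:**
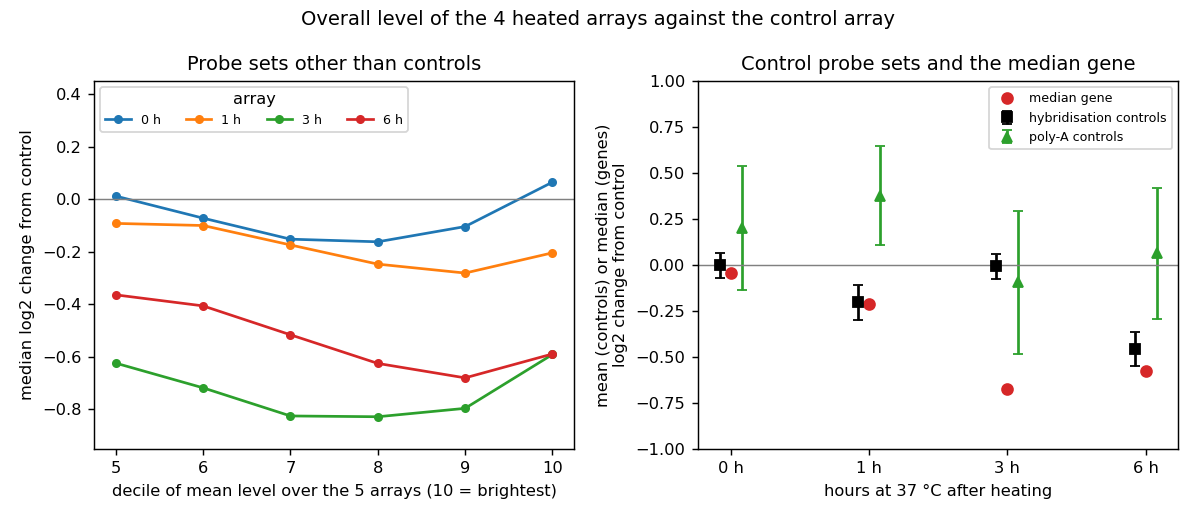
Left, median log2 change from control (vertical axis) of all probe sets other than controls, without the floor, with 1 line for each heated array. Probe sets are grouped by level on the horizontal axis (deciles 5 to 10 of mean log2 intensity). Right, mean log2 change from control of the hybridisation controls and of the poly-A controls, with the SD over probe sets, beside the median gene, which lay at -0.68 log2 at 3 h where the hybridisation controls lay at -0.009 log2.

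Directly after heating (0 h), genes of chaperones, the proteins that keep other proteins folded, led the rises. HSPA6, a member of the HSP70 family that is hardly made without stress, went from an intensity of 228 to 7623, a 34.4-fold rise. DNAJB1, which delivers unfolded proteins to HSP70, rose 8.28-fold from 1227 to 9851, and BAG3, which releases proteins from HSP70, rose 9.05-fold. In the other direction, SREBF1, which encodes a transcription factor of lipid synthesis, fell at least 17.9-fold, and MYC, which drives growth and ribosome production, fell 5.09-fold from 5167 to 986.

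Several chaperone families moved at 0 h. Among 9 measured HSP70 and HSP110 genes, 3 rose, which were HSPA6, HSPA1L (3.62-fold) and HSPH1, an exchange factor for HSP70 (2.67-fold, 2422 to 6264). The median of this list lay 0.54 log2 above the median gene, at percentile 100 of random lists matched on expression, and at percentile 59.5 without a floor, which ends that call. Of 23 HSP40 genes, 4 rose, namely DNAJA4 (12.6-fold), DNAJB1, DNAJA1 (2.37-fold) and DNAJB2 (at least 2.38-fold), and the list median of 0.19 log2 was not called apart (percentile 96.6), while its mean was (0.48 log2, percentile 100). The small heat shock and BAG list had a median of 0.43 log2 (percentile 99.97, but 28.9 without probe sets that can bind several transcripts), with rises of BAG3, of HSPB1, which binds unfolding proteins without ATP (2.46-fold, 3665 to 8735), and of CRYAB, its relative (at least 2.18-fold). The HSP90 list had a median of 0.35 log2 (percentile 99.98, but 96.6 without probe sets that can bind several transcripts). In it CHORDC1, an HSP90 co-chaperone, rose 2.25-fold, while HSP90AA1, the inducible HSP90, was 1.36-fold higher at intensities above 10000.

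Partners and targets of heat shock factors had a median of 0.71 log2 (percentile 100, but 93.9 without probe sets that can bind several transcripts). SERPINH1, the chaperone of collagen in the endoplasmic reticulum (ER), rose at least 17.0-fold from below the floor to 282, IER5, which activates heat shock factor 1, rose 7.31-fold, and RGS2, a brake on G protein signalling, rose 7.21-fold. None of the 9 chaperonin genes passed 2-fold, yet their median was 0.36 log2 (percentile 99.6, but 94.2 by their mean), with CCT3 at 1.31-fold and HSPD1 at 1.21-fold. ZFAND2A, which fits the proteasome to stress, rose 4.82-fold, the phosphatase DUSP1 4.75-fold, the cytoskeletal gene ACTRT3 6.81-fold and COL2A1, a collagen of cartilage, from 18.6 to 199. Without any single gene past 2-fold, the proteasome list lay at 0.30 log2 (percentile 99.98) and the mitochondrial ribosome list at 0.26 log2 (percentile 100). Ribosome biogenesis lay at 0.22 log2 (percentile 98.8, but 61.2 without probe sets that can bind several transcripts).

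Cholesterol synthesis and the SREBP pathway had the lowest list median at 0 h of the 33 lists, -0.85 log2, below all 10000 matched random lists. Of its 21 genes, 7 fell, among them INSIG1, which holds SREBP in the ER (4.33-fold, 6399 to 1435), SREBF2, the main regulator of sterol synthesis (2.52-fold), STARD4, a sterol carrier (3.00-fold), and LSS, which makes lanosterol (2.12-fold). Immediate early genes, which answer growth signals within minutes, had a median of -0.48 log2 (percentile 0.01), with falls of MYC and IER2 (3.86-fold, 3015 to 757) against a rise of KLF2, a factor that quiets monocytes (3.35-fold). Targets of ATF4 and CHOP in the integrated stress response had a median of -0.36 log2 (percentile 0.06, but 36.1 without probe sets that can bind several transcripts). In that list CTH, which makes cysteine, fell 4.13-fold, SLC7A11, which imports cystine, fell 4.41-fold, and PPP1R15A, which restarts translation, rose 2.80-fold.

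Among the largest falls at 0 h by the naming rule, GPR183, which guides cells along oxysterols, fell 7.97-fold (864 to 105), GPR65, an acid sensor, fell 7.29-fold, RGS1, which stops chemokine signals, fell 6.38-fold, and MAML2, a coactivator of Notch, fell at least 5.17-fold. Myeloid identity genes as a list were not called (median 0.01 log2, percentile 36.2). NF-kB targets were split and their median was not called apart (percentile 30.2). TNFAIP3 (2.52-fold), NFKBIZ (2.30-fold) and PTGS2 (2.35-fold), which are feedback and prostaglandin genes of inflammation, rose, while CCL2, a monocyte attractant, fell 3.30-fold from 2422 to 711, and TNF fell 2.07-fold. Of 27 glycolysis and hypoxia genes, 5 fell, with the glucose transporter SLC2A3 at 3.12-fold and HK2 at 2.01-fold, and ALDOC rose 2.49-fold. The list was not called by its median (-0.05 log2, percentile 3.86) but was by its mean (-0.25 log2, percentile 0.09). S100A8, a calcium-binding protein of myeloid cells, rose 3.34-fold from 154 to 498.

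Smaller shifts below the median gene were called for mitotic genes (-0.06 log2, percentile 0.62), splicing factors (-0.07 log2, percentile 1.37), although the splicing kinase CLK1 rose 2.32-fold, and zinc finger genes (-0.16 log2, percentile 0.59, with 23 of 316 fallen). In all, 218 of 12985 genes were at least 2-fold higher and 591 lower as deposited, and 250 and 516 relative to the median gene, 26.9% and 32.6% of calls being rises. In simulated data with normal noise of the measured SDs, among 12430 simulated genes 120 unchanged ones were at least 2-fold higher and 131 lower by chance, and 16 passed 4-fold. The real noise had more extreme values, so these numbers may be too low. Single genes near 2-fold are therefore uncertain, rises more than falls. Of the 14 list calls at 0 h, those of immediate early genes, cholesterol synthesis, mitochondrial ribosomes and the proteasome held under every alternative that was run.

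After 1 h at 37 °C, leading chaperone genes stood high, and the lists of ATF4 and CHOP targets and of NF-kB targets lay above matched lists. HSPA6 rose 51.3-fold to 10115 and DNAJA4, an HSP40 partner, rose 36.7-fold from 34.0 to 1073. CHAC1, a target of ATF4 and CHOP that breaks down glutathione, rose 4.58-fold, and NFKBIZ, an inducible regulator of NF-kB target genes, rose 5.11-fold. MYC, at 787, was 5.66-fold below control, while the cholesterol synthesis list was no longer apart from matched lists (median -0.08 log2, percentile 17.6).

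Other chaperone rises at 1 h were those of BAG3 (16.7-fold), DNAJB1 (10.7-fold, to 11350), HSPA1L (6.14-fold), HSPH1 (3.92-fold), HSPB1 (2.72-fold), DNAJA1 (2.53-fold), DNAJB2 (at least 3.89-fold), CRYAB (at least 6.85-fold) and FKBP4, a co-chaperone of steroid receptors (2.65-fold). SERPINH1 rose at least 25.6-fold, RGS2 12.3-fold, IER5 8.98-fold and ZFAND2A 9.23-fold. MRPL18, a mitochondrial ribosomal protein that also serves stress translation, rose 2.36-fold. The medians were 0.47 log2 for HSP70 and HSP110, 0.31 log2 for HSP90 and 0.84 log2 for the heat shock factor partners, each at percentile 100. Chaperonins had a median of 0.25 log2 (percentile 99.6, but 91.8 by their mean). The small heat shock list, with a median of 0.08 log2 (percentile 78.0), and the HSP40 list, with 0.10 log2 (percentile 96.3), were not called by their medians but were by their means (0.72 log2 at percentile 99.97 and 0.51 log2 at percentile 100).

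The ATF4 and CHOP list lay at 0.24 log2 (percentile 99.98) at 1 h, with 4 of 20 genes risen, among them CHAC1, PPP1R15A (3.67-fold) and ATF3, a stress-induced repressor (3.23-fold). Aminoacyl-tRNA synthetases, which are ATF4 targets as well, lay at 0.22 log2 (percentile 99.99) without a gene past 2-fold. NF-kB targets lay at 0.22 log2 (percentile 99.6), with rises of NFKBIZ, TNFAIP3 (4.33-fold) and PTGS2 (3.02-fold) and a fall of CCL2 (4.02-fold). HMOX1, which degrades heme, rose 3.86-fold, although the NRF2 list as a whole was not called (percentile 5.61). The killer genes PMAIP1 (3.06-fold, to 2167) and BMF (2.77-fold), which free BAX and BAK from their guards, rose. CFLAR, which blocks death receptors, rose 3.45-fold on its brightest probe set, while the lowest of its 12 probe sets was at -0.68 log2 as deposited. The BCL2 family median was at -0.01 log2 (percentile 59.3). KLF2 rose 5.71-fold and FOSB, an AP-1 subunit, rose 2.95-fold.

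Falls at 1 h included GPR183 (11.9-fold, to 62.8), GPR65 (5.94-fold), RGS1 (4.48-fold), FJX1, a secreted kinase-like protein (4.86-fold), TNFRSF12A, the receptor of TWEAK (4.28-fold), IER2 (2.89-fold), CEBPA, the master factor of the myeloid lineage (2.33-fold), the ribosome assembly factor RRS1 (2.46-fold) and the cyclin CCNE2 (2.37-fold). Zinc finger genes lay at -0.17 log2, below all matched lists, and splicing factors at -0.12 log2 (percentile 1.05), with CLK1 3.54-fold up. Ribosomal protein genes lay at 0.21 log2 (percentile 100, but 85.1 after quantile normalization) and NADH dehydrogenase genes at 0.11 log2 (percentile 98.1). Counts were 249 higher and 632 lower of 12735 as deposited, 413 and 331 relative to the median gene and 232 and 523 after median centring, so the share of rises was 28.3%, 55.5% or 30.7% by scaling. The calls of HSP70 and HSP110, HSP90, heat shock factor partners, ATF4 targets and zinc finger genes held under every alternative.

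**Figure D2:**
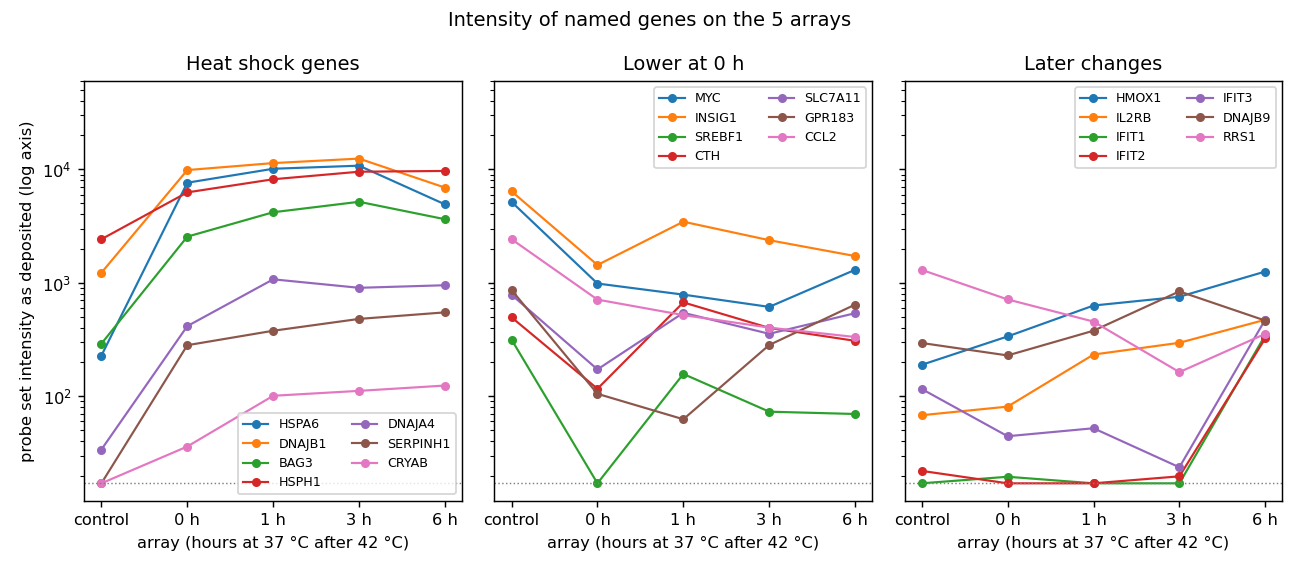
Intensity as deposited (logarithmic vertical axis) on the 5 arrays in order of time (horizontal axis) for heat shock genes, genes dimmer at 0 h and genes that moved later, with the floor of 17.1 as a dotted line. DNAJB1 stood at 1227 in control cells and at 12437 at 3 h, MYC at 5167 and 613, and IFIT1 reached 346 at 6 h.

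After 3 h of recovery, chaperone genes led the rises again, the ER list was called above matched lists and the ribosome biogenesis list below them. HSPA6 rose 75.3-fold to 10772, DNAJB1 16.2-fold to 12437 and HSPH1 6.28-fold to 9528. As deposited, HSPA6 was at 5.47 log2 at 1 h and 5.56 log2 at 3 h, and DNAJB1 at 3.21 and 3.34 log2. Most of the growth in their folds since 1 h therefore came from the scaling. Every relative fold at 3 h is shifted in this way by the median gene's -0.68 log2. DNAJB9, an ER co-chaperone that is induced by misfolded proteins, rose 4.55-fold from 295 to 840. RRS1, which assembles the large ribosomal subunit, fell 4.99-fold from 1300 to 163, and the myeloid factor CEBPA fell 3.79-fold from 3511 to 580.

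Further rises at 3 h were those of SERPINH1 (at least 44.9-fold), DNAJA4 (42.5-fold), BAG3 (28.4-fold, to 5176), ZFAND2A (21.8-fold, to 4168), RGS2 (12.8-fold), IER5 (12.4-fold), HSPA1L (10.8-fold), HSPA4L, an HSP110 gene (3.94-fold), HSPB1 (4.02-fold), DNAJA1 (3.67-fold), MRPL18 (3.56-fold) and CRYAB (at least 10.4-fold). KLHL25, an adaptor for protein breakdown, rose 12.4-fold from 45.2 to 351, and CRTAM, an adhesion receptor of T and NK cells, rose from 21.7 to 163. List medians were 0.91 log2 for HSP70 and HSP110, 0.65 log2 for HSP90, 0.52 log2 for chaperonins and 1.37 log2 for heat shock factor partners, at percentile 99.86 for chaperonins and 100 for the others. By their mean, chaperonins were not called (percentile 96.3). HSP90AA1 was 2.04-fold above control relative to the median gene and 1.28-fold as deposited, so its rise hangs on the scaling. The small heat shock list lay at 0.30 log2 (percentile 97.6), a call that held under 3 of 11 alternatives, and HSP40 genes lay at 0.04 log2 by their median (percentile 70.1) and at 0.53 log2 by their mean (percentile 100).

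The ER list lay at 0.23 log2 at 3 h (percentile 99.02) and held 1 gene of 22 that rose as deposited, DNAJB9. Of the ATF4 and CHOP targets (0.27 log2, percentile 99.6), CHAC1 rose 4.39-fold, PPP1R15A 3.62-fold and ATF3 3.31-fold. HMOX1 rose 6.35-fold to 753, PMAIP1 3.37-fold, KLF2 5.70-fold and FOSB 3.91-fold. NF-kB targets lay at 0.25 log2 (percentile 99.7), with 5 genes at least 2-fold higher relative to the median gene and none as deposited, while CCL2 (3.77-fold) and TNF (at least 3.19-fold) fell. Ribosomal protein genes lay at 0.50 log2 (percentile 100, but 62.4 after quantile normalization) and the proteasome at 0.32 log2 (percentile 99.9). Epithelial and fibroblast markers were called at 0.65 log2 (percentile 98.0) on 5 measured genes, a call that held under 5 of 11 alternatives. Any alternative with fewer than 5 measured genes gave no percentile and is counted as not holding the call. Among these markers COL1A1, a collagen of connective tissue, rose at least 11.8-fold on its brightest probe set. Another of its 3 probe sets lay at -0.55 log2 as deposited, near the median gene (-0.68 log2).

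Ribosome biogenesis lay at -0.29 log2 at 3 h, below all matched lists, with POLR1C, a subunit of RNA polymerases I and III, falling 2.31-fold beside RRS1. CEBPE, which completes granulocyte maturation, fell 2.43-fold, although the myeloid list was not called at 3 h (median 0.10 log2, percentile 71.4). MYC (5.28-fold, to 613), its antagonist MNT (5.57-fold), TNFRSF12A (6.06-fold), the corepressor NACC2 (5.59-fold), TNFAIP8L2, which restrains immune signalling (5.34-fold), the vesicle gene SFT2D3 (5.67-fold) and IBA57, which builds mitochondrial iron-sulfur clusters (at least 6.26-fold), fell as well. Mitotic genes lay at -0.07 log2 (percentile 2.15), with falls of ASPM, a spindle pole protein (2.18-fold), and GTSE1 (2.37-fold). Splicing factors lay at -0.27 log2 (percentile 0.01), with 8 of 26 above the median gene, among them CLK1, which rose 3.87-fold, and 33 of 301 zinc finger genes fell (median -0.32 log2, below all matched lists).

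The general drop of the 3 h array dominates its counts, with 110 of 12267 genes higher and 3264 lower as deposited, against 439 and 572 relative to the median gene and 337 and 726 after median centring, or 3.3%, 43.4% and 31.7% rises among calls. Of the 15 list calls, those of HSP70 and HSP110, HSP90, heat shock factor partners, ATF4 targets, NF-kB targets, ribosome biogenesis and zinc finger genes held under every alternative.

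By 6 h, HSPA6 stood lower than at 3 h, at 4912 (32.1-fold above control), while SERPINH1 (at least 47.9-fold, to 549) and DNAJA4 (41.8-fold) were high. A trio of interferon-induced genes whose proteins bind viral RNA was up against control, namely IFIT1 (at least 30.2-fold, to 346), IFIT2 (21.9-fold, 22.0 to 324) and IFIT3 (6.11-fold, 116 to 475), while their relative IFIT5 was at least 2.91-fold higher relative to the median gene and at least 1.95-fold as deposited. HMOX1 rose 9.91-fold from 189 to 1257, and IL2RB, a receptor chain for interleukins 2 and 15, rose 10.4-fold from 68.1 to 473. The lists of ribosome biogenesis and cholesterol synthesis lay below matched lists.

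Chaperone rises at 6 h included BAG3 (18.6-fold), ZFAND2A (16.5-fold), CRYAB (at least 10.8-fold), DNAJB1 (8.40-fold, to 6904), HSPH1 (5.96-fold), HSPA4L (5.68-fold), HSPB1 (3.61-fold), DNAJA1 (3.57-fold), MRPL18 (3.31-fold) and HSPA1L (3.19-fold), as well as IER5 (6.55-fold) and RGS2 (6.03-fold). HSF1, the factor that switches heat shock genes on, fell 2.11-fold from 291 to 92.1 on 1 probe set. Its other probe set moved by -0.21 log2 as deposited, which lies above the median gene (-0.58 log2), so the probe sets disagree. The medians were 0.97 log2 for HSP70 and HSP110, 0.60 log2 for HSP90, 0.68 log2 for small heat shock genes and 1.09 log2 for heat shock factor partners, all at percentile 99.9 or above, while the medians of HSP40 genes (0.13 log2, percentile 96.4, against percentile 100 for their mean) and chaperonins (0.25 log2, percentile 95.8) were not called. ADM, a vasodilator peptide induced by low oxygen, rose 3.25-fold, COL2A1 rose 14.5-fold and KLF2 3.44-fold. Among 22 interferon-induced genes, IFIT1, IFIT2 and IFIT3 rose. The list as a whole was not called by its median (0.26 log2, percentile 94.8) but was by its mean (0.73 log2, percentile 100).

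Ribosome biogenesis reached -0.58 log2, below all matched lists, with falls of POLR1A, the large subunit of RNA polymerase I (2.51-fold), RRS1 (2.45-fold), UTP20, which takes part in the cleavage of ribosomal RNA precursors (2.24-fold), and POLR1C (2.10-fold). Cholesterol synthesis lay at -0.53 log2, again below all matched lists, with SREBF1 (3.03-fold), INSIG1 (2.49-fold) and LSS (2.49-fold) fallen. Myeloid identity genes lay at -0.31 log2 (percentile 0.14), with CEBPA 2.03-fold and CEBPE 2.33-fold lower, and mitochondrial ribosome genes at -0.16 log2 (percentile 1.95), with MRPS26 2.10-fold and MRPS18A 2.05-fold lower. HYAL2, a hyaluronan-cleaving enzyme of the cell surface, fell at least 10.6-fold (270 to 15.7), CCL2 4.88-fold, GPR84, a receptor for fatty acids on macrophages, 4.86-fold, PRAM1, a myeloid adaptor, 4.09-fold, the centromere protein gene CENPB 4.02-fold, CCND2, a cyclin of the G1 phase, 2.80-fold, MYC 2.66-fold (to 1303) and the RNA helicase DDX5 2.42-fold.

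Mitotic genes were called above matched lists at 6 h (0.20 log2, percentile 99.97). Relative to the median gene, UBE2C, which helps to break down cyclins, was 1.91-fold and AURKA, a spindle kinase, 1.79-fold higher, while 3 genes of the list were at least 2-fold lower as deposited. Other upward calls at 6 h were those of ATF4 targets (0.23 log2, percentile 98.9, held under 3 of 11 alternatives), NF-kB targets (0.30 log2, percentile 99.1), NRF2 targets (0.21 log2, percentile 98.6), the BCL2 family (0.19 log2, percentile 99.1), ribosomal proteins (0.22 log2, percentile 99.99, but 70.9 after quantile normalization), NADH dehydrogenase (0.14 log2, percentile 98.4), zinc finger genes (0.10 log2, percentile 99.5) and epithelial and fibroblast markers (1.06 log2, percentile 99.95, on 6 genes). Counts were 111 higher and 2570 lower of 12489 as deposited, 573 and 468 relative to the median gene, and 246 and 1006 after median centring, or 4.1%, 55.0% and 19.6% rises among calls. The calls of HSP70 and HSP110, small heat shock genes, heat shock factor partners, mitotic genes, zinc finger genes, cholesterol synthesis and ribosome biogenesis held under every alternative.

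**Figure D3:**
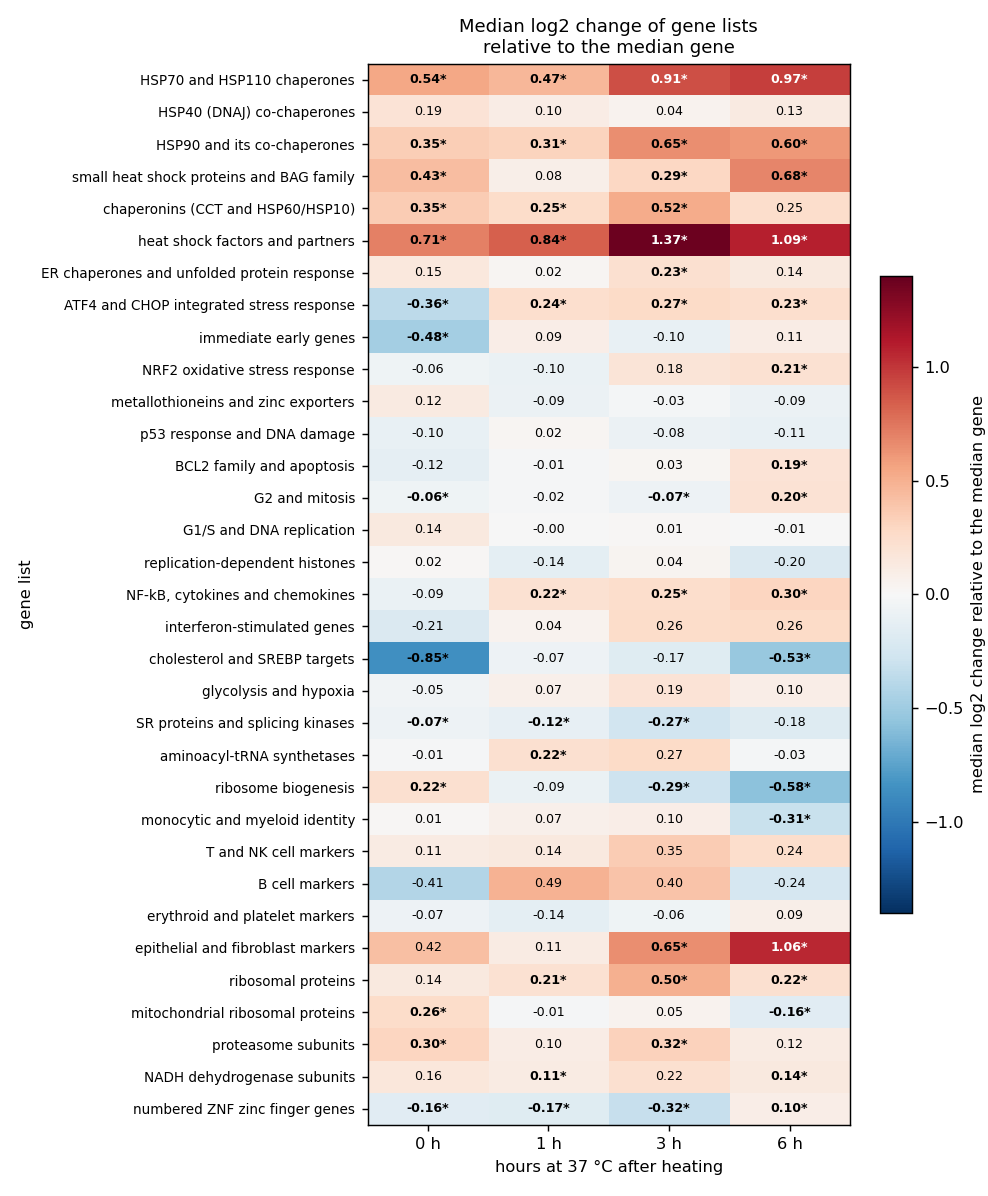
Median log2 change of the 33 gene lists (vertical) relative to the median gene at the 4 recovery times (horizontal), with an asterisk where a list was called apart from matched random lists. Cholesterol synthesis went from -0.85 log2 at 0 h to -0.08 at 1 h and -0.53 at 6 h, and ribosome biogenesis went from 0.22 log2 at 0 h to -0.58 at 6 h.

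Comparisons between consecutive times do not use the control array. They reuse the heated arrays of the comparisons above and are not separate evidence. A single outlying array would show as a change and its reversal. Between 0 and 1 h, SREBF1 rose at least 10.3-fold, to 157, and CTH rose 6.48-fold, from 117 to 672. S100A8 fell 3.49-fold over the same hour, from 498 to 127, and GSTM3, a glutathione transferase, fell at least 3.09-fold. Of 12917 genes, 251 were higher and 220 lower as deposited, 422 and 102 relative to the median gene (median -0.17 log2) and 246 and 153 after median centring, giving 53.3%, 80.5% and 61.7% rises.

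From 1 to 3 h, GPR183 rose 6.22-fold (62.8 to 283), CD69, an early activation antigen of leukocytes, 5.39-fold (55.1 to 215) and RGS1 4.57-fold. KLF15, a factor of amino acid and fat metabolism, fell at least 3.92-fold, FBXO31, which marks cyclin D1 for breakdown, fell 3.70-fold, and ANKRD13D, a ubiquitin-binding gene of receptor uptake, fell 3.76-fold. Counts were 23 higher and 1145 lower of 12099 as deposited, 134 and 191 relative to the median gene (median -0.46 log2) and 168 and 198 after median centring, so rises were 2.0%, 41.2% or 45.9% of calls.

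From 3 to 6 h, IFIT1 (at least 19.0-fold), IFIT3 (18.8-fold, 23.7 to 475) and IFIT2 (15.4-fold) rose together, as did CDC37L1, an HSP90 co-chaperone (at least 4.42-fold). ID3, an inhibitor of differentiation factors, fell at least 4.11-fold, DUSP1 fell 4.09-fold from 648 to 169, and TNFSF14, a cytokine of lymphocytes known as LIGHT, fell 3.87-fold. Counts were 514 higher and 99 lower of 11675 as deposited, 366 and 157 relative to the median gene (median 0.09 log2) and 240 and 393 after median centring, so rises went from 83.8% of calls as deposited to 37.9% after median centring.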

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

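All tests in this part were chosen after the results were seen.

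The median gene was at -0.68 log2 on the 3 h array and at -0.58 log2 on the 6 h array. The hybridisation controls gave no sign of lower hybridisation or scanner sensitivity at 3 h, as they moved by -0.009 log2 (SD 0.07). This SD is over probe sets and does not measure differences between arrays in the amount of control. The control mean also moved by -0.20 log2 at 1 h, so with 1 array at each time lower sensitivity at 3 h is not excluded. At 6 h the hybridisation controls moved by -0.46 log2 (SD 0.09), so lower sensitivity may account for much of that array's drop and this explanation is open. The ratios of 3' to 5' signal of GAPDH and ACTB gave no sign of RNA degradation at 3 h, as their geometric mean was 0.998 times that of control cells. From control to 3 h, GAPDH went from 1.13 to 1.07 and ACTB from 1.30 to 1.36. Both transcripts are very bright, so degradation of dimmer ones is not excluded. Whether less messenger RNA was present in the total RNA at 3 h is open, because the poly-A controls moved by -0.094 log2 with an SD of 0.39. The labels do not say whether these controls were added or how much cRNA was loaded, so a difference in loading cannot be told apart from it.

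Control probe sets for 28S ribosomal RNA were mostly brighter after heating as deposited, the 5' set by 9.53-fold at 0 h (210 to 2000), 9.09-fold at 1 h, 5.00-fold at 3 h and 1.60-fold at 6 h, the middle set by 3.29-fold at 0 h (959 to 3152) and 2.96, 2.54 and 2.43-fold at 1, 3 and 6 h, and the dim 3' set by at least 1.99, 3.39 and 1.36-fold at 0, 1 and 3 h, below the floor at 6 h as in control cells. The 18S sets moved by -0.59 log2 (SD 0.49) at 0 h and so gave no sign of more carry-over of all ribosomal RNA. They were dim in control cells (87.65, 47.79 and 25.28), so such carry-over is not excluded at 0 h. The 3 sets of 18S were 1.59, 1.49 and 2.24-fold higher at 1 h and 1.70, 1.81 and 3.18-fold higher at 3 h, so it is open at those times. Unprocessed or fragmented ribosomal RNA could raise 28S sets, and the precursor's probe sets moved by 0.50 and 1.07 log2 at 0 h and by 2.29 and 3.16 log2 at 1 h. They were still at 2.226 and 2.478 log2 at 3 h and at 2.115 and 1.974 log2 at 6 h, when the 5' set of 28S was down to 1.60-fold. With the lowest of these values at 0.50 log2, this explanation is open.

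IFIT3 was at -2.29 log2 at 3 h and at 2.03 log2 at 6 h as deposited, and with 1 array at each time this difference could not be tested against replicates. All 5 probe sets of IFIT1, IFIT2 and IFIT3 were higher at 6 h than at 3 h, by at least 3.09 log2. Their agreement cannot exclude noise of single dim probe sets, because the naming rule already required a gene's probe sets to share direction. IFIT1 had only 1 probe set, while IFIT2 and IFIT3 each had more than 1. A rise shared by most interferon-induced genes was not seen, since the median of the 19 other listed genes was 0.17 log2 (SD 0.56) relative to the median gene. IFIT5 among them was at 1.54 log2 or more. With IFIT1, IFIT2 and IFIT3 included, the list had a mean of 0.73 log2 at 6 h (percentile 100). An interferon response limited to some of these genes is therefore open.

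Among probe sets without a single gene, 6 of 6198 were at least 8-fold higher than control at 0 h, 13 of 6215 at 1 h, 4 of 5574 at 3 h and 3 of 5855 at 6 h.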

How the results depend on the processing

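Counts of genes past the threshold moved with the floor, the fold threshold and the scaling. In what follows, pairs give genes higher and lower. With the floor at the 40th percentile (intensity 10.3), 612, 520, 201 and 276 genes were higher than control at 0, 1, 3 and 6 h and 969 were lower at 1 h. Consecutive steps then gave 514 and 653 from 0 to 1 h, 94 higher from 1 to 3 h, and 842 and 243 from 3 to 6 h. With the floor at the 70th percentile (intensity 68.0), counts against control were 51 and 325 at 0 h, 85 and 347 at 1 h, 60 and 2160 at 3 h, and 49 higher at 6 h. The steps gave 69 and 40, 6 and 391, and 202 and 28.

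Without a floor, counts against control were 2718 and 2540, 2415 and 3021, 1873 and 6644, and 2057 and 5507 at 0, 1, 3 and 6 h, and the steps gave 2137 and 2839, 1747 and 4288, and 3365 and 2320. At a threshold of 3-fold, counts were 41 and 89, 68 and 91, 44 and 724, and 42 and 451 against control, with 39 and 15, 3 and 117, and 40 and 12 for the steps. When the floor was added to every value instead, 648 genes were lower from 1 to 3 h and 330 higher from 3 to 6 h.

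Relative to the median gene, counts against control were 413 and 331 at 1 h, 439 and 572 at 3 h, and 573 and 468 at 6 h, and the steps gave 422 and 102, 134 and 191, and 157 lower from 3 to 6 h. After median centring they were 337 and 726 at 3 h, 246 and 1006 at 6 h, 168 and 198 from 1 to 3 h, and 240 and 393 from 3 to 6 h. Median centring with the higher floor gave 50 and 289 at 0 h, 81 and 280 at 1 h, 377 lower at 3 h and 608 lower at 6 h, with 71 and 31, 44 and 22, and 72 higher for the steps. Quantile normalization gave 366 lower at 0 h, 344 lower at 1 h, 430 and 489 at 3 h, 422 and 494 at 6 h, 211 and 186 from 1 to 3 h, and 311 and 344 from 3 to 6 h, and 4 lists were called below matched lists at 1 h. Centring on the hybridisation controls gave 351 lower at 1 h, 352 and 751 at 6 h, and 420 and 102, 13 and 2117, and 1852 and 23 for the steps.

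Without probe sets that can bind several transcripts, 4 lists were called above and 2 below matched lists at 0 h, and 2 below at 3 h. The small heat shock list then moved to percentile 28.9 at 0 h, so its call at that time rests on such probe sets. The 0 h calls of ATF4 and CHOP targets (percentile 36.1), heat shock factor partners (percentile 93.9), HSP90 (percentile 96.6), ribosome biogenesis (percentile 61.2), mitotic genes, splicing factors (percentile 22.5) and zinc finger genes were lost in the same way, as was that of HSP70 and HSP110 without a floor (percentile 59.5). The small heat shock call at 3 h held under 3 of 11 alternatives, with percentile 46.9 without a floor. With the median over the probe sets of each gene, splicing factors moved to percentile 57.0 at 1 h, so that call is lost. Quantile normalization ended the calls of ribosomal proteins at 1, 3 and 6 h (percentiles 85.1, 62.4 and 70.9). The mean in place of the median called the HSP40 list at all 4 times. In all it added 18 list calls and ended 17. Among those ended were chaperonins and splicing factors at 0, 1 and 3 h, the latter at percentiles 13.1, 45.2 and 6.03. Of 57 list calls, 23 held under all 11 alternatives that could move a percentile. An alternative that left a list without a percentile was counted as not holding the call. Epithelial and fibroblast markers at 6 h thus held under 8 of 11 alternatives, although their lowest percentile was 97.64.

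Single genes turned with the probe set as well. Without probe sets that can bind several transcripts, and as deposited, FKBP4 was at -0.23 log2 at 0 h and at -0.23 log2 at 6 h. RRP12 was at 0.30 log2 at 6 h and PLAUR at 0.25 log2 at 0 h. Each went against the direction of its brightest probe set, although FKBP4 at 6 h stayed above the median gene of -0.58 log2. CD22 was at -0.007 log2 at 0 h with the median over its probe sets.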

Other observations

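The test of antisense transcripts in this part was written down before its result was seen, and the genes and lists were picked after the values were seen.

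Groups whose medians stayed within the range of matched lists at all 4 times included metallothioneins, which bind zinc and copper (medians of 0.12, -0.09, -0.03 and -0.09 log2 relative to the median gene at 0, 1, 3 and 6 h), p53 targets (-0.10, 0.02, -0.08 and -0.11 log2) and genes of the G1/S transition (0.14, 0.00, 0.01 and -0.01 log2). By their mean, p53 targets were called at 3 h (percentile 97.96). Histone genes were at 0.02, -0.14, 0.04 and -0.20 log2, with the last at percentile 2.56, while their mean at 6 h was at percentile 0.13. Within these lists GADD45B, which slows the cell cycle under stress, rose 2.96-fold at 0 h and 2.88-fold at 1 h, and UNG, which removes uracil from DNA, fell 2.09-fold at 6 h. Markers of T and NK cells were at 0.11, 0.14, 0.35 and 0.24 log2, of B cells at -0.41, 0.49, 0.40 and -0.24 log2 and of erythroid cells at -0.07, -0.14, -0.06 and 0.09 log2, on 8 genes at most. No call was made by the median, while the B cell mean at 1 h was at percentile 97.88. At 3 and 6 h the B cell list had 4 measured genes and got no percentile, so it could not be called. Glycolysis and hypoxia genes were at 0.07, 0.19 and 0.10 log2 from 1 to 6 h, and ALDOC, a brain form of aldolase, rose 3.57-fold at 1 h while HK2, the hexokinase of proliferating cells, fell 2.65-fold at 6 h.

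The proteasome list was at 0.30, 0.10, 0.32 and 0.12 log2 at 0, 1, 3 and 6 h, with calls at 0 and 3 h (percentiles 91.4 at 1 h and 93.9 at 6 h), and ER genes were at 0.15, 0.02, 0.23 and 0.14 log2, with a call at 3 h (percentiles 82.9, 64.1 and 97.0 at the other times). Immediate early genes were at 0.09, -0.10 and 0.11 log2 from 1 to 6 h, after -0.48 log2 at 0 h. Aminoacyl-tRNA synthetases were at -0.01, 0.27 and -0.03 log2 at 0, 3 and 6 h. CIRBP, an RNA-binding protein made in the cold, fell 2.13-fold at 6 h, and splicing factors were at -0.18 log2 at that time (percentile 2.92).

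Heating might increase transcription outside coding genes. If so, genes named as antisense, intronic or divergent transcripts could lie above matched lists early on. Their medians were -0.02 log2 at 0 h (426 genes, percentile 24.5) and 0.07 log2 at 1 h (395 genes, percentile 36.6). No rise above genes of similar level was thus seen for the genes named in this way. The comparison cannot show a rise shared with those genes, so the idea is not excluded. For other transcripts it is open. Of probe sets without a single gene, 173 of 6198, 430 of 6215, 44 of 5574 and 89 of 5855 were at least 2-fold higher as deposited at 0, 1, 3 and 6 h, which was not compared with genes of the same level, and which transcripts they detect is not known here. At 3 and 6 h the percentiles were 42.0 and 7.61.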
